A study of Homo sapiens with 6 samples.

How the data were processed

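The samples were labelled as neutrophils from blood of 6 patients, 3 treated with abatacept + CNI and 3 with CNI. Per the labels' protocols, cryopreserved cells were thawed, total RNA was extracted with a MagMAX mirVana kit, and libraries were made with a NEBNext Ultra II Directional kit, which keeps the strand. Isolation and purity of the cells were not given in the sources used here. The submitters' processing notes name STAR, Salmon and DESeq2 without a role, order or version. The genome build and annotation were not given in the sources used here, so no coordinates are printed. The deposited table held TPM values per gene, named by the file itself as TPM, for 38552 gene rows and 6 libraries. Each column summed to 1e+06 over the rows, so a higher share of one gene lowers the TPM of every other gene. TPM is scaled by transcript length and library total and keeps no read counts, so sequencing depth was unknown and no counting interval was given. Some genes that most cells use, HPRT1 and TBP among them, were listed at 0 in some libraries, so a 0 was read only as listed at 0. Globin genes of adult blood and mitochondrially encoded genes were not analysed here, and the total of every library is over the rows used, without them.

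Groups came from the sample titles and columns were matched to samples by library name. A set of 101 rows was left out before any step: genes on a fixed list of Y-linked genes, XIST and its neighbours and some X-linked genes that escape X inactivation, polymorphic HLA and KIR genes, genes with common deletions or variants of expression, antigen receptor segments, and the ABO, Rh and glycophorin A, B and E blood group genes. Other X-linked and blood group genes stayed in. Genes with at least 1 TPM in at least 3 libraries were tested, which left 9709. TPM was tested as log2(TPM + 1) in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A count model was not used because TPM is no count. All tests were two-sided.

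Before the data were examined, 36 gene lists were fixed, of which 34 had at least 5 genes tested. They were tested with camera in limma at a preset correlation of 0.01, which compares the genes of a list with all other genes, and beside it with an estimated correlation and with fry, which tests whether the genes move on balance one way. Lists overlap and are not independent tests. Values adjusted over a list alone are limma p-values of the main fit, adjusted within that list and not across lists. They test a gene against no change, not against the other genes. List scores are the mean log2(TPM + 1) of the tested members per library. Scores and shares of TPM were compared with exact permutation tests over the 20 assignments of 3 against 3 patients, whose smallest p is 0.1. The correlation of the NET score with the monocyte score was set, after it was seen, beside that with random lists of the same size, drawn from genes outside both lists. The relations within groups used scores with the group mean removed and all 36 orders of the libraries within their groups.

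Genes were named by a rule fixed before the data were examined. It took up to 10 genes in each direction past the adjusted threshold, with groups that did not overlap and a mean of at least 5 TPM in the higher group, by largest log2 difference, filled to 10 by smallest p among genes that met the other criteria. It added PADI4, ELANE, MPO, PRTN3, CTSG, CYBB, NCF1, GSDMD, CD80 and CD86, and the 3 tested members of smallest p of each list described. It left out the rows named above, clone and locus names, small RNA genes and pseudogenes. Some genes that the rule takes are not reported here.

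The steps were tested on simulated data for this comparison, with 9709 genes at the real means and 200 changed genes. Spreads were capped at the median spread, and changed genes were taken from those with a mean log2(TPM + 1) above 3. Genes were drawn independently of each other, so the simulation cannot show calls that correlation between genes can give. Of 100 genes changed by 2 on the log2 scale 56% were recovered, and of 100 changed by 4, 100%, with 3 false calls. A simulated list shifted by 1.5 passed camera and 0 other lists did. Alternatives covered the pseudocount, the filter, scaling between libraries, each library left out, a replicate block, library weights, a neutrophil marker covariate, and other limma and list tests.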

Results

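RNA was measured by sequencing in blood samples labelled as neutrophils from 6 transplant patients at day 14. Of these, 3 had received a regimen based on a calcineurin inhibitor (CNI), a drug class that blocks T cell activation, and 3 had received abatacept in addition. Abatacept is a fusion of the extracellular part of CTLA4 with an antibody Fc part, and it binds CD80 and CD86. Each library came from a separate patient, and libraries are named here by group and replicate number. The values were TPM, a measure of transcript abundance scaled for length, which sum to the same total in every library and keep no sequencing depth, so depth was unknown. The series title places the samples in a study of graft-versus-host disease prophylaxis, endothelial injury and NETosis, the release of neutrophil extracellular traps (NETs). The single comparison asked how transcripts of these samples differed between abatacept + CNI and CNI. How the cells were isolated and how pure they were was not given in the sources used here, and erythroid transcripts were abundant, so the values need not be those of neutrophils alone.

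The most abundant transcripts in these libraries included several of the erythroid lineage. UBB, a polyubiquitin gene, averaged 65931 TPM over the 6 libraries and the ferritin gene FTL 34802 TPM. ALAS2, the erythroid enzyme of heme synthesis, stood at 10289 ± 1961 TPM with abatacept + CNI and at 12259 ± 1085 TPM with CNI (mean ± SD, n = 3 in each group). AHSP, the chaperone of alpha hemoglobin, stood at 8665 ± 4317 and 11107 ± 1997 TPM. The receptor for granulocyte colony-stimulating factor, CSF3R, stood at 62.0 ± 52.9 and 96.3 ± 92.9 TPM, and the neutrophil and monocyte gene S100A8 at 1480 ± 1833 and 3497 ± 3241 TPM. These genes were chosen for their abundance or cell type after their values were seen. The 15 erythroid marker genes took 5.47 ± 0.771% of all TPM with abatacept + CNI and 5.97 ± 0.661% with CNI (exact permutation test, two-sided, p = 0.5). This share is of a total without globin genes of adult blood and mitochondrial genes, which were not analysed here. Mature neutrophil marker genes took 0.0326 ± 0.0305% and 0.0861 ± 0.0872% (exact permutation p = 0.5). The 10 most abundant genes took 33.1 ± 3.70% of TPM with abatacept + CNI and 26.4 ± 2.85% with CNI (exact permutation p = 0.1, the smallest that 3 against 3 patients allows). The abatacept + CNI libraries had 9315, 9306 and 9494 genes at 1 TPM or more, and the CNI libraries 7710, 11908 and 16130 (exact permutation p = 0.4).

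The libraries did not separate by treatment alone. The first principal component held 57.1% of the variance and set CNI replicate 2, at 117, and CNI replicate 3, at 48.5, apart from the other 4 libraries, which lay between -63.9 and -29.0. CNI replicate 1 correlated across genes with the 3 abatacept + CNI libraries at Pearson's r of 0.912 to 0.920, against 0.799 to 0.834 for CNI replicate 2 and 0.879 to 0.885 for CNI replicate 3. Genes are not independent replicates in these coefficients.

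Among 9709 genes tested, 1 passed limma with Benjamini-Hochberg adjustment at 0.05. This was SNORA100, a small nucleolar RNA outside the rule for named genes and chosen after its values were seen. It was listed at 0 in all 3 abatacept + CNI libraries and at 87.0, 1322 and 457 TPM in CNI replicates 1, 2 and 3 (limma adjusted p = 0.000152). The next smallest adjusted p was 0.104. At an unadjusted p under 0.05, 82 genes were higher and 1193 lower with abatacept + CNI. These counts were 103 and 336 without CNI replicate 2, and 89 and 3346 without CNI replicate 1. The groups did not overlap for 1696 genes, or 17.5% of those tested, and 1570 of these were lower. Chance gives 10% on average, but genes are correlated, and of the 9 other splits of the libraries into 3 against 3, counted after the fact, 1 had 2255 such genes and another 1687. Those splits gave 1615 and 1163 genes at an unadjusted p under 0.05 by limma, against 1275 for the real groups. Of all genes tested 82.7% were lower, and the median gene differed by -0.65 on the log2(TPM + 1) scale, a scale that understates the change of low genes. With median-of-ratios scaling the median was -0.11, the unadjusted calls split into 345 higher and 464 lower, and 6 genes passed (4 higher, 2 lower). With quantile normalization the median was -0.01, the split was 448 higher and 371 lower, and 4 genes passed (3 higher, 1 lower).

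IFI27, an interferon-induced gene, was the most abundant of the genes with the smallest p in the higher direction. It stood at 26420 ± 12860 TPM with abatacept + CNI and 2670 ± 3067 TPM with CNI, a log2 difference of 3.84 ± 0.66 (SE), higher in 3 of 3 patients than in any CNI patient (limma adjusted p = 0.114). Its adjusted p was 0.0310 with median-of-ratios scaling, and it also passed without abatacept + CNI replicate 2 (0.0213) or 3 (0.00455) and without CNI replicate 1 (0.0444) or 2 (0.000415). It did not pass with quantile normalization (limma adjusted p = 0.291), without abatacept + CNI replicate 1 (0.506) or without CNI replicate 3 (0.585). Nor did it pass with pseudocount 0.1 (0.400) or 5 (0.0969), no filter (0.160) or the 5 TPM filter (0.370). It also failed with rescaling without ribosomal protein genes (0.103), limma without trend (0.359) and robust eBayes (0.366). It passed with the neutrophil marker covariate (2.03e-05) and with array weights (2.48e-05), which did not converge. It also passed with the replicate block (8.2e-18), but that block matches separate patients by number alone, so the value is no paired evidence. POLR2J2, a member of a family of near-identical RNA polymerase subunit copies, was listed at 0 in all CNI libraries and at 11.1, 9.22 and 31.0 TPM in abatacept + CNI replicates 1, 2 and 3 (limma adjusted p = 0.104). Its value is uncertain because reads can be split between such copies. The log2 difference was 3.37 for C10orf10, 2.99 for FAM83A, 2.13 for CBFA2T2, a transcriptional corepressor, and 2.09 for CITED2, a transcriptional coregulator. It was 1.93 for NET1, 1.77 for SVBP, which binds vasohibin, 1.36 for TMCC2 and 1.28 for MZT2B. Limma adjusted p was 0.236 for C10orf10 and 0.377 for the other 7.

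In the lower direction, EIF4EBP1, a repressor of cap-dependent translation, ranged from 0 to 1.28 TPM with abatacept + CNI and from 12.7 to 25.2 TPM with CNI (log2 difference -3.40, limma adjusted p = 0.172). C1orf54 was listed at 0 in all 3 abatacept + CNI libraries and at 5.95, 10.8 and 19.3 TPM in the CNI libraries (limma adjusted p = 0.121). POLB, a DNA repair polymerase, was also listed at 0 in those 3 libraries and at 1.75, 10.2 and 5.27 TPM with CNI (limma adjusted p = 0.377). EIF3C, a translation initiation subunit, was listed at 0, 0 and 28.7 TPM with abatacept + CNI and at 73.7, 78.2 and 92.6 TPM with CNI (limma adjusted p = 0.319). Its near-identical copy EIF3CL was listed at 49.97, 36.2 and 7.74 TPM against 0, 23.1 and 0, so the split between both copies is uncertain. The actin-binding thymosin gene TMSB4X stood at 356 ± 72.0 and 2187 ± 1889 TPM (log2 difference -2.23), and the tetraspanin gene CD82 at 20.8 ± 10.5 and 91.8 ± 25.6 TPM (-2.16). The log2 difference was -2.82 for PHB2, a prohibitin, -2.80 for the splicing factor SRSF9, -2.93 for COMMD6 and -2.90 for the mitochondrial ribosomal gene MRPS34. Limma adjusted p was 0.377 for these 6 genes.

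**Figure D1:**
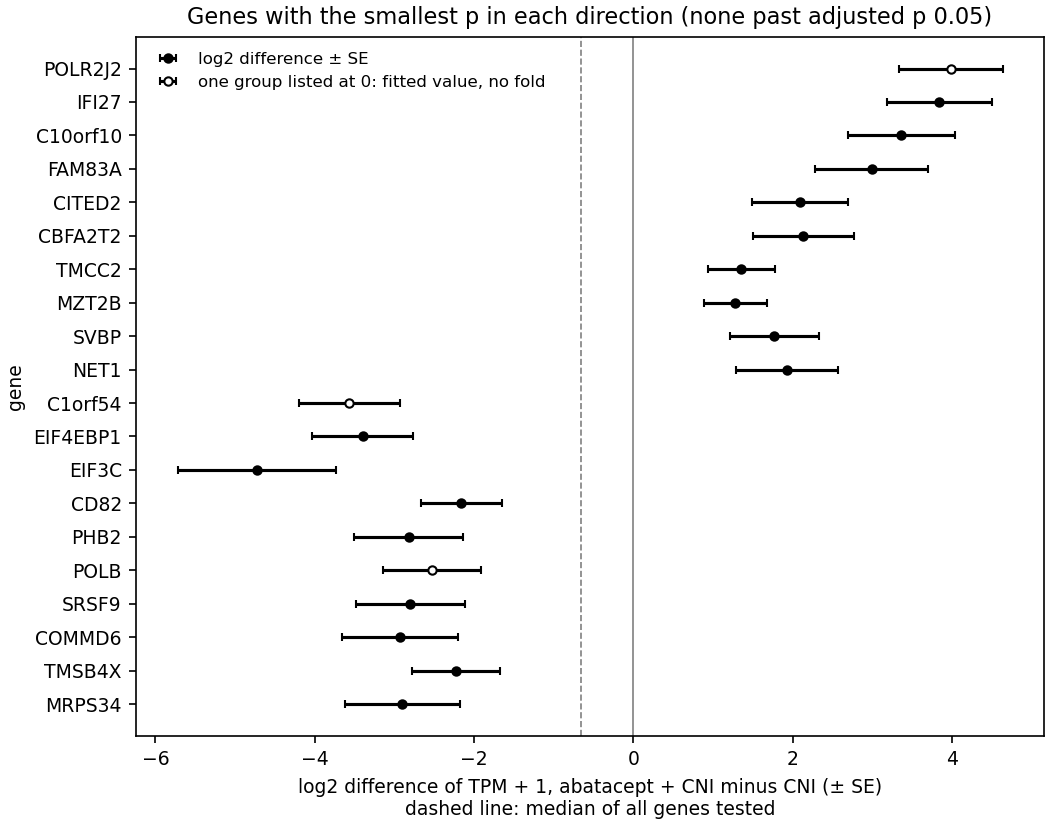
The log2 difference of TPM + 1 (abatacept + CNI minus CNI, bars ± SE from limma, n = 3 patients in each group) for the 10 genes of smallest p in each direction whose groups did not overlap, among genes that the naming rule takes. SNORA100, which passed, is outside that rule and not shown. None of the genes shown passed adjusted p 0.05. Open circles are genes listed at 0 in 1 whole group, and the dashed line is the median of all genes tested, -0.65.

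Genes of the machinery of NET formation fell as a list relative to the other genes. Of 34 members tested, 33 were lower with abatacept + CNI and 10 of these had an unadjusted p under 0.05, but no member passed over all genes or adjusted over the list alone. The mean log2 difference was -1.19, or -0.54 relative to the median of all genes (camera adjusted p = 0.00882, and adjusted p = 0.914 with an estimated correlation). PADI4, the peptidylarginine deiminase that citrullinates histones in NETosis, stood at 3.63 ± 1.90 TPM with abatacept + CNI and 21.1 ± 22.9 TPM with CNI. Its log2 difference was -1.84 ± 0.74 (SE, limma adjusted p = 0.377). The groups did not overlap, but the gap was narrow, from 5.2361 TPM in abatacept + CNI replicate 3 to 5.9998 TPM in CNI replicate 3. PADI4 stood at 9.91 TPM in CNI replicate 1 and at 47.4 TPM in CNI replicate 2. Groups without overlap in the lower direction were also common, at 1570 of all 9709 genes tested. The log2 difference was -2.20 for ITGB2 and -1.93 for ITGAM, the subunits of the integrin Mac-1, and -2.17 for the inflammatory caspase CASP1 (limma adjusted p = 0.377 for each). GSDMD, the pore-forming gasdermin, differed by -1.04 (limma adjusted p = 0.509) and MPO, myeloperoxidase, by -0.52 (0.613). The neutrophil protease genes ELANE, PRTN3 and CTSG and the abatacept ligand CD80 were below the filter, and CTSG was listed at 0 in all 6 libraries and ELANE in 5. The other ligand, CD86, differed by -1.13 (limma adjusted p = 0.455).

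The NET score, the mean log2(TPM + 1) of the list per library, was 2.75 ± 0.489 with abatacept + CNI and 3.95 ± 1.22 with CNI (exact permutation p = 0.3). CNI replicate 2 had a score of 5.29, and CNI replicate 1, at 2.90, lay within the abatacept + CNI range of 2.20 to 3.13. Without CNI replicate 2 the NET list had a camera adjusted p of 0.375, and without abatacept + CNI replicate 2 of 0.0738, in a range of 2.18e-07 to 0.914 over 20 alternatives. Its mean was -0.53 without CNI replicate 2, with 25 of 30 members lower and 0 at an unadjusted p under 0.05 (limma). The camera adjusted p was 0.522 with mature neutrophil markers as covariate and 0.687 with array weights. The NET score minus the mature neutrophil score, after leaving out their shared gene, was -0.289 ± 0.810 with abatacept + CNI and -0.209 ± 0.965 with CNI (exact permutation p = 0.9). Across the 6 libraries the NET score correlated with the monocyte score at Pearson's r = 0.977 (exact permutation p = 0.00417, 0.00833 adjusted over the 2 relations computed) and Spearman's rank coefficient of 0.943 (exact permutation p = 0.0167). Without CNI replicates 2 and 3, the 2 libraries farthest from the median monocyte score, its r was 0.810. The NET score also correlated at r = 0.953 with the median log2(TPM + 1) of all genes tested, and with 10000 random lists of 26 genes, not matched for expression, at a median r of 0.930, where 6.32% of the lists reached the r of the monocyte list. The coefficient is therefore not specific to monocyte genes. With the mature neutrophil score r was 0.799 (exact permutation p = 0.0569, also after adjustment) and the rank coefficient 0.714 (exact permutation p = 0.136). Without CNI replicate 2 and abatacept + CNI replicate 2 that r was -0.357, so the relation was not seen without those libraries. They were left out as the 2 farthest from the median mature neutrophil score, which narrows the range and by itself can lower r. With group means removed, a check added after the fact, r was 0.963 with the monocyte score (exact permutation within groups p = 0.0556, 0.111 adjusted over 2 relations) and 0.740 with the mature neutrophil score (exact permutation p = 0.194, also after adjustment). The smallest p of the 36 orders is 0.0278, and random lists of the same sizes had a median r of 0.893 and 0.895. Whether both coefficients differ was not tested.

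Lists of neutrophil genes had negative mean log2 differences in the main scaling. Azurophil granule genes fell relative to the other genes, with 9 of 9 lower and a mean of -1.52 (camera adjusted p = 0.0483, and adjusted p = 0.914 with an estimated correlation). Only these 9 of the 19 azurophil genes with values passed the filter. LYZ, lysozyme, differed by -2.40 and SRGN, the granule proteoglycan serglycin, by -1.97, and both fell when adjusted over the list alone (0.0406 for each, limma). LYZ is also on the monocyte list, where no gene passed adjusted over the list alone. CD63, a granule membrane tetraspanin, differed by -1.87 (limma adjusted p = 0.377). Gelatinase granule and secretory vesicle genes also fell relative to the other genes, with 23 of 24 lower and a mean of -1.15 (camera adjusted p = 0.0496, and adjusted p = 0.914 with an estimated correlation). CTSZ, a lysosomal cysteine protease, stood at 70.5 ± 6.12 against 195 ± 52.3 TPM, and FCN1, ficolin 1, at 9.69 to 49.7 against 36.3 to 607 TPM (limma adjusted p = 0.377 for each). Specific granule genes (mean -1.29, 10 of 10 lower), mature neutrophil markers (-1.13, 23 of 23) and neutrophil precursor genes (-0.81, 10 of 10) did not pass camera (adjusted p = 0.0630, 0.0920 and 0.457). Without CNI replicate 2 the mature neutrophil mean was -0.33 with 15 of 23 lower, or 0.05 relative to the median of all genes (camera adjusted p = 0.796), and the means were -0.95 for azurophil, -0.61 for gelatinase, -1.01 for specific granule and -0.82 for precursor genes. LTF, lactoferrin, differed by -1.99 and CHI3L1 by -2.08 (limma adjusted p = 0.377 for each). NADPH oxidase subunits did not pass either, with 6 of 8 lower and a mean of -0.85 (camera adjusted p = 0.775). Their mean without CNI replicate 2 was -0.14 with 5 of 8 lower, or 0.24 relative to the median of all genes. The log2 difference was -1.62 for CYBA, -1.33 for CYBB and -1.28 for NCF1, which has near-identical pseudogene copies (limma adjusted p = 0.377, 0.400 and 0.507). The azurophil call was lost without abatacept + CNI replicate 1 (0.0833) or 2 (0.0738) and CNI replicate 1 (0.0918) or 2 (0.132), and the gelatinase call without the same 4 libraries (0.331, 0.532, 0.656 and 0.330) and with median-of-ratios scaling (0.0577). Both were also lost with pseudocount 0.1 (0.123 and 0.0586) and the 5 TPM filter (0.119 and 0.167), the azurophil call with rescaling without ribosomal protein genes (0.191), and the gelatinase call with pseudocount 5 (0.0845). With array weights both calls were lost (0.291 and 0.0837), and with the mature neutrophil markers as covariate the gelatinase call was (0.584).

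Platelet, monocyte, T cell and NK cell markers fell as lists, while erythroid markers did not pass. Platelet and megakaryocyte markers fell relative to the other genes, with 20 of 21 lower and a mean of -1.69 (camera adjusted p = 2.8e-06, and adjusted p = 0.914 with an estimated correlation). Adjusted over the list alone, 13 of them fell, although 0 passed over all genes. Of these, TUBB1, a platelet tubulin, stood at 5.87 ± 1.98 TPM with abatacept + CNI and 32.5 ± 16.7 TPM with CNI, and PF4, platelet factor 4, at 9.59 ± 3.98 and 69.2 ± 69.4 TPM (limma adjusted over the list alone, 0.0271 for each). Monocyte and macrophage markers (mean -1.70, 26 of 26 lower), T cell markers (-1.49, 18 of 18) and NK and cytotoxic cell markers (-1.31, 18 of 19) also fell relative to the other genes. Camera adjusted p was 0.000118 for monocyte, 0.00513 for T cell and 0.00893 for NK cell markers, and adjusted p = 0.914 for each of them with an estimated correlation. CPVL, a monocyte carboxypeptidase, differed by -2.72, the T cell antigen CD7 by -2.25, and GNLY, the cytotoxic granule protein granulysin, by -2.50 (limma adjusted p = 0.377 for each). Erythroid markers did not pass (camera adjusted p = 0.173), with 9 of 15 lower and a mean of -0.18, which was 0.56 with median-of-ratios scaling. They passed as higher than the other genes with that scaling (camera adjusted p = 0.00438, 13 of 15 higher) and without abatacept + CNI replicate 2 (0.0392). SLC4A1, the red cell anion exchanger band 3, differed by -0.91 and CA1, carbonic anhydrase 1, by 0.53 (limma adjusted p = 0.377 and 0.475). Without CNI replicate 2 the mean was -0.85 for monocyte, -0.93 for T cell, -1.12 for NK cell and -1.21 for platelet markers. The scores of CNI replicate 1 lay within the abatacept + CNI range for monocyte, T cell and NK cell markers (2.47, 0.986 and 1.80). With CNI replicates 2 and 3 both left out, T cell markers turned to the higher direction, but CNI replicate 1 alone gives no spread between CNI patients. The T cell call was lost without CNI replicate 2 (0.0516) or 3 (0.137), and the NK cell call without abatacept + CNI replicate 1 (0.0762) or CNI replicate 3 (0.193) and at the 5 TPM filter (0.147).

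**Figure D2:**
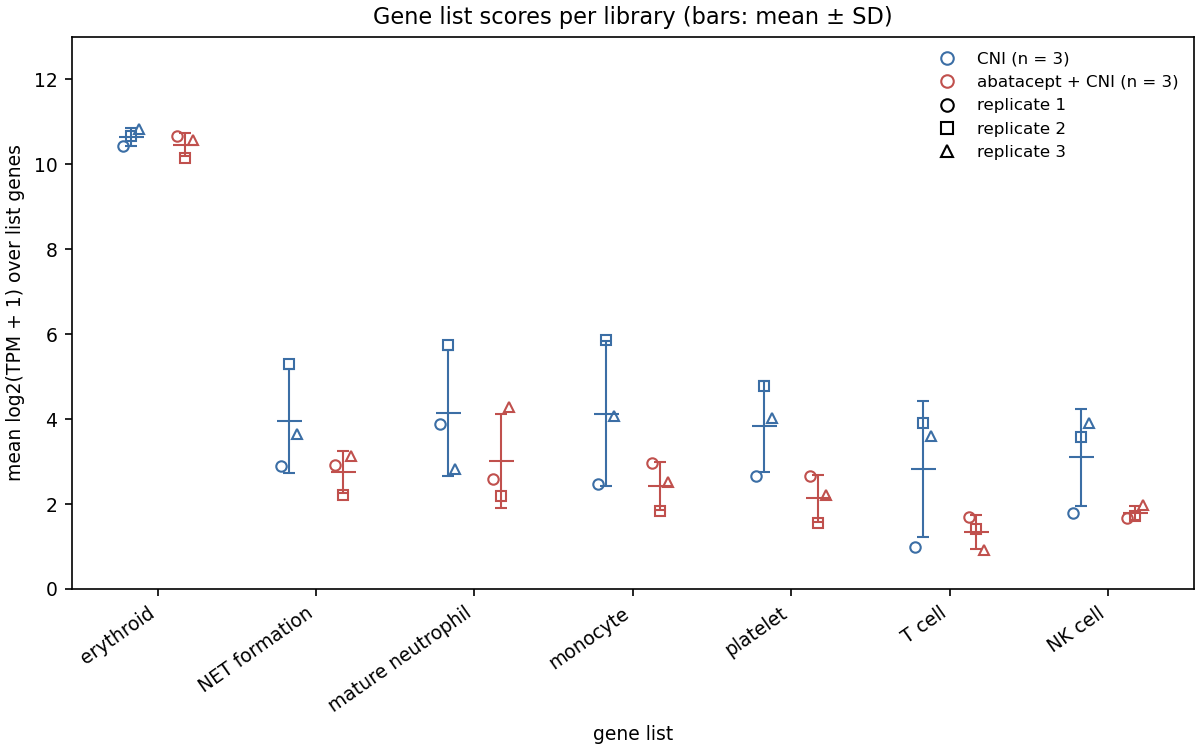
Mean log2(TPM + 1) over the genes of each of 7 lists per library, with CNI in blue and abatacept + CNI in red, symbols for the replicate and bars for mean ± SD (n = 3). Erythroid scores lie near 10.5 in both groups, while CNI replicate 2 has the highest NET, mature neutrophil, monocyte, platelet and T cell scores.

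Genes of adhesion and rolling on endothelium fell relative to the other genes, with 22 of 23 lower and a mean log2 difference of -1.40 (camera adjusted p = 0.000434, and adjusted p = 0.914 with an estimated correlation). TLN1, the integrin activator talin, differed by -2.05 and ITGB1 by -1.88 (limma adjusted p = 0.377 for each). Complement receptors, regulators and components fell relative to the other genes, with 17 of 17 lower and a mean of -1.37 (camera adjusted p = 0.0144, and adjusted p = 0.914 with an estimated correlation). C1RL differed by -2.10 and CFD, complement factor D, by -2.74, and both fell when adjusted over the list alone (0.0383 for each, limma). Without CNI replicate 2 the mean was -0.89 for adhesion and -0.81 for complement genes. The adhesion call was lost with the neutrophil marker covariate (0.0739) and with array weights (0.0854). The complement call was lost without abatacept + CNI replicate 2 (0.0738) or CNI replicate 1 (0.0616) or 2 (0.122), at the 5 TPM filter (0.119), with the covariate (0.225) and with array weights (0.575).

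Both interferon lists had negative mean log2 differences in the main scaling, the sign of the type I mean turned with scaling, and the difference between the lists was not tested. Genes of the interferon gamma response and class II antigen presentation fell relative to the other genes, with 21 of 21 lower and a mean of -1.31 (camera adjusted p = 0.0120, and adjusted p = 0.914 with an estimated correlation). PSMB8, an immunoproteasome subunit, differed by -2.57 and fell when adjusted over the list alone (0.0324, limma). WARS, a tryptophanyl-tRNA synthetase, differed by -2.05, and TAP1, a peptide transporter, by -1.64 (limma adjusted p = 0.377 for each). Type I interferon genes rose relative to the other genes by camera (adjusted p = 0.0231, and adjusted p = 0.914 with an estimated correlation), although the mean of -0.29 and median of -0.50 were negative and 8 of 33 members were higher. Relative to the median of all genes the mean was 0.36, and without IFI27 the other 32 genes did not pass (camera adjusted p = 0.0983 over 2 lists tested after the fact). IFI27 rose when adjusted over the list alone (0.00116, limma), ISG15, a ubiquitin-like modifier, differed by 2.08, and USP18, its deconjugating protease, by -1.52 (limma adjusted p = 0.377 for both). The interferon gamma mean without CNI replicate 2 was -0.52 with 17 of 20 lower, or -0.14 relative to the median of all genes. The call was lost there (0.430), at the 5 TPM filter (0.0769), with the covariate (0.175) and with array weights (0.291). The type I mean was 0.32 with 20 of 33 higher with median-of-ratios scaling, 0.38 with 21 of 33 with quantile normalization and 0.67 with 23 of 29 without CNI replicate 2. The type I call was lost with no filter (0.999) and pseudocount 5 (0.0696), without abatacept + CNI replicate 1 (0.0524) or CNI replicate 1 (0.280) or 3 (0.510), with median-of-ratios scaling (0.0577) and with quantile normalization (0.0631).

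Glycolysis genes fell relative to the other genes, with 20 of 22 lower and a mean of -1.21 (camera adjusted p = 0.0120, and adjusted p = 0.914 with an estimated correlation). Adjusted over the list alone, 6 fell and 1 rose. PGK1, phosphoglycerate kinase, differed by -2.49, the pyruvate kinase PKM by -2.24 and the aldolase ALDOA by -1.75 (limma adjusted over the list alone, 0.0389 for each). The member that rose was SLC2A1, the glucose transporter of red cells and many other cells, at 1.46, named after its value was seen. The glycolysis mean was -0.67 without CNI replicate 2, where the call was lost (0.136), and the call was also lost with the covariate (0.105) and with array weights (0.112). Nuclear genes of oxidative phosphorylation (mean -0.87, 32 of 34 lower), glucocorticoid response genes (-0.94, 14 of 18) and immediate early genes (-1.03, 19 of 22) did not pass camera (adjusted p = 0.0920, 0.408 and 0.413). Without CNI replicate 2 the means were -0.52 (28 of 34 lower), -0.51 (14 of 17) and -0.14 (13 of 21), in that order. UQCRC1, a complex III subunit, differed by -1.96, ANXA1, annexin A1, by -2.41, and the transcription factor KLF4 by -1.89 (limma adjusted p = 0.377 for each).

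**Figure D3:**
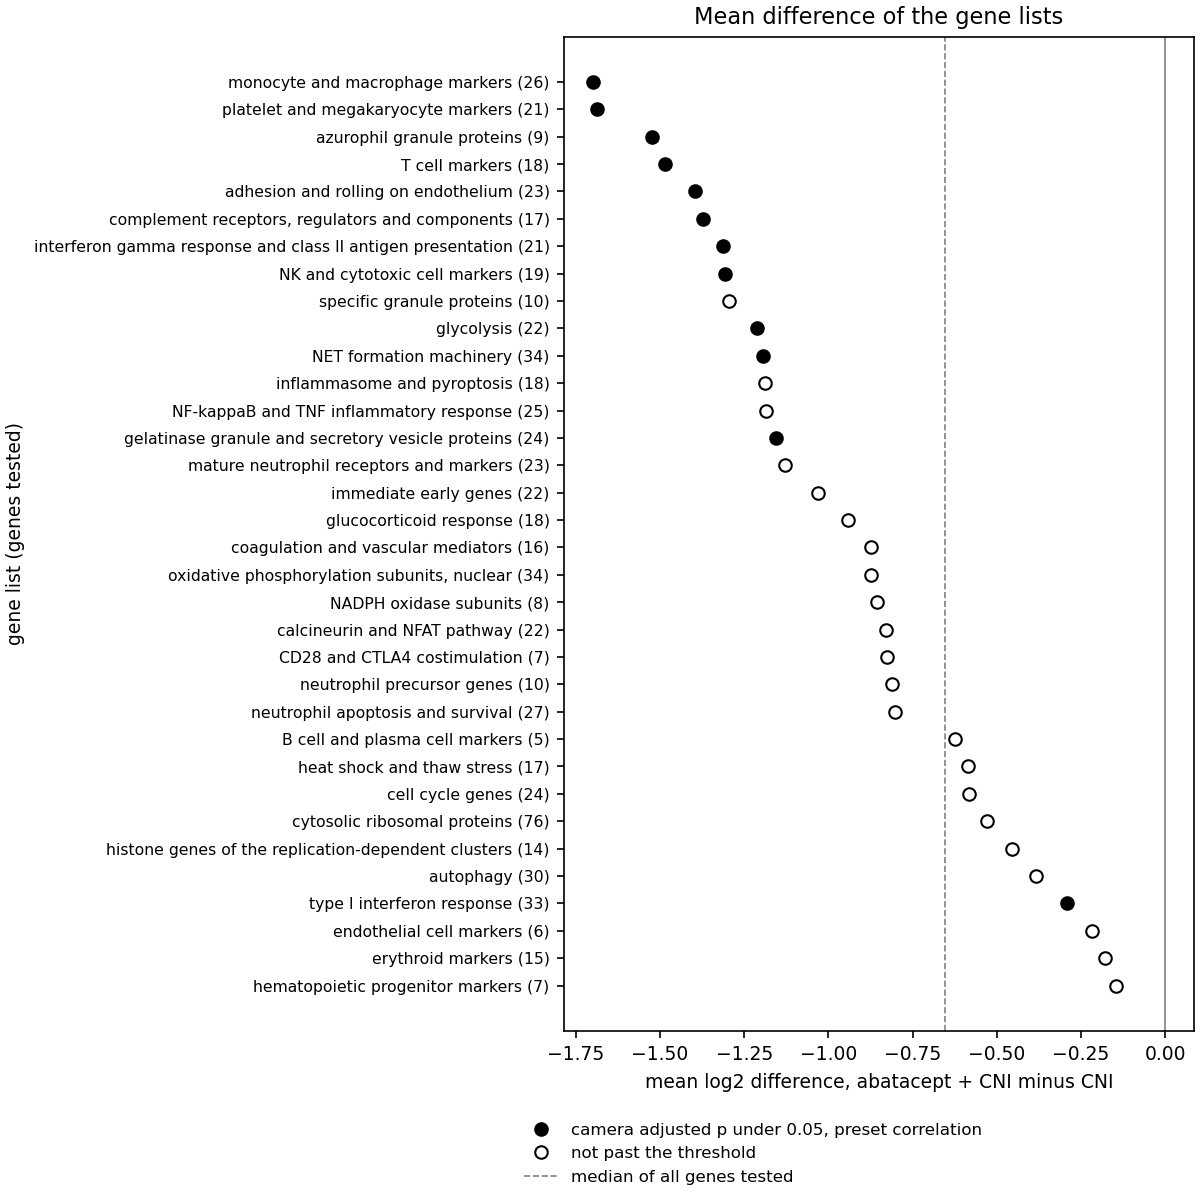
Mean log2 difference (abatacept + CNI minus CNI, n = 3 patients each) of the 34 lists tested, with the number of genes tested in parentheses; filled circles passed camera with a preset correlation. In this scaling, where 82.7% of all genes tested were lower, each of the 34 means lies below 0 (8 lie above 0 with median-of-ratios scaling), the 12 filled circles include 11 lists lower and 1 higher than the other genes, and the dashed line marks the median of all genes, -0.65.

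In all, 12 of 34 lists passed camera with the preset correlation, none did with an estimated correlation (smallest adjusted p = 0.914, and 0 at an unadjusted p under 0.05) and none by fry (smallest adjusted p = 0.364, and 2 at an unadjusted p under 0.05). The estimated correlation within the 12 lists ran from 0.251 for azurophil granule genes to 0.884 for T cell markers, and was 0.705 for the NET list. The preset was 0.01, so the calls depend on it. Over 19 or 20 alternatives for each of the 12 lists, the adjusted p ranged from 4.15e-13 to 0.999. The alternatives include a fit with 1 CNI library, which gives no spread between CNI patients. The call held in the same direction in 17 alternatives for the platelet and for the monocyte list, 15 for adhesion, 14 each for glycolysis, T cell and NK cell lists, 13 each for NET and interferon gamma, 11 each for type I interferon and complement, 9 for azurophil and 8 for gelatinase granule genes. Mature neutrophil markers, which did not pass as reported, passed as lower in 5 of 20 alternatives and as higher in 2. The 20 include the fit with this list's own mean as covariate, which fixes its mean difference by construction and does not test it. Specific granule genes passed as lower in 8 of 19. The count of 1 gene became 804, of which 782 were lower, without CNI replicate 1, and 0 without CNI replicate 3 by limma, where 624 genes had an unadjusted p under 0.05. It was 2, 5 and 6 without abatacept + CNI replicates 1, 2 and 3, and 6 without CNI replicate 2.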

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

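The neutrophil marker covariate and the fit without CNI replicates 2 and 3 together were chosen after seeing the data, and the other alternatives were planned. The fit without CNI replicates 2 and 3 leaves 1 CNI library and no spread between CNI patients. Only directions and differences are given from it, although it is among the alternatives in the counts and ranges over alternatives. The count of 1 gene past the threshold was 1 with pseudocounts 0.1 and 5, both other filters, rescaling and limma without trend. It was 6 with median-of-ratios scaling, 4 with quantile normalization, 2 with robust eBayes and 12 with the covariate. It was 4544 with array weights, which did not converge and gave CNI replicate 3 a weight of 15.6. With 1 library left out it ranged from 0 to 804, and SNORA100 failed the filter without any CNI library. The 12 lists became 24 with no filter, 6 at 5 TPM, 0 with an estimated correlation and 0 by fry, and 6 to 16 with 1 library left out. The NET list had an adjusted p of 0.687 with array weights, 0.522 with the covariate, 0.911 without CNI replicates 2 and 3, 0.914 with an estimated correlation, 0.364 by fry, and 7.93e-05 to 0.375 with 1 library left out. Directions reversed for gelatinase granule genes with array weights (adjusted p 0.0837) and the covariate (0.584), type I interferon genes by fry (0.776) and T cell markers without CNI replicates 2 and 3 (0.107). For type I interferon genes the 2 directions answer different questions, since fry tests against no change and camera against the other genes. The lower direction by fry has the sign of the main mean, -0.29, so the genes themselves did not change sign there. Log2 differences reversed to 0.10 for CYBB, 1.04 for GSDMD and 0.0068 for CYBA without CNI replicates 2 and 3. They reversed to 1.67 and 0.34 for NCF1 with array weights and the covariate, and to 0.022 for CXCR4 with array weights. Scores reversed to 0.32 for type I interferon and 0.56 for erythroid genes with median-of-ratios scaling. With 1 library left out the type I interferon score difference ranged from -0.83 to 0.58. The 0.58, without CNI replicate 2, is over the 33 genes of the main filter. The mean of 0.67 given above is over the 29 genes that passed the filter without that library. The cause of these changes was not tested. Of other values for named genes 1279 kept direction and side of the threshold and 138 gained it. Most of the 138 came from array weights, which did not converge, or from the fit without CNI replicate 1. In that fit the smallest limma adjusted p was 0.0444. Of the values for called lists 156 kept both and 79 lost the call. Shares of the most abundant genes and genes detected were run only with 50 genes or 5 TPM and with each library left out, and kept direction there. With the patient number as a replicate block 41 genes and 17 lists passed. With the group mean of each gene removed, however, same-numbered libraries correlated at 0.0081, -0.151 and -0.0498, and no library correlated best with its own number. In the rescaling no mitochondrial genes were left out. TPM gives no depth, so low genes have no stated precision.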

Other observations

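Other inflammatory and immune lists did not pass camera as reported, although inflammasome genes passed as lower in 6 of 20 alternatives and NF-kappaB genes in 4. Inflammasome and pyroptosis genes had a mean log2 difference of -1.19 with 18 of 18 lower (camera adjusted p = 0.0630), and NF-kappaB and TNF response genes -1.18 with 20 of 25 lower (0.173). Genes of the calcineurin and NFAT pathway, the target of CNI drugs, had a mean of -0.83 with 21 of 22 lower (0.333), and genes of CD28 and CTLA4 costimulation -0.83 with 6 of 7 lower (0.676). Coagulation and vascular mediators had a mean of -0.87 with 15 of 16 lower (0.457). B cell and plasma cell markers had a mean of -0.62 with 4 of 5 lower (0.777). Without CNI replicate 2 the mean was -0.52 for inflammasome, -0.44 for NF-kappaB, -0.43 for calcineurin and -0.42 for coagulation genes. It was -0.45 for costimulation genes (4 tested there) and 0.15 for B cell markers (2 tested there). Eosinophil and basophil markers had 4 of 19 genes tested, too few for camera. Of these, 2 fell when adjusted over the list alone (0.0181 for each, limma): IL3RA, at -1.81, and CCR3, an eotaxin receptor, at -1.39. Both were low, with means of 0.337 against 3.77 TPM for IL3RA and 0.0884 against 1.84 TPM for CCR3. Over all genes limma adjusted p was 0.377 for each, and CCR3 passed the filter through the CNI libraries alone.

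Cell state lists did not pass as reported. In the main scaling 82.7% of all genes tested were lower, and the signs of several means turned with another scaling. Neutrophil apoptosis and survival genes had a mean of -0.80 (22 of 27 lower, camera adjusted p = 0.579), cell cycle genes -0.58 (22 of 24, 0.907), heat shock genes -0.59 (14 of 17, 0.777) and autophagy genes -0.38 (22 of 30, 0.191). Cytosolic ribosomal protein genes had a mean of -0.53 (68 of 76, 0.458) and replication-dependent histone genes -0.46 (9 of 14, 0.333). With median-of-ratios scaling the mean was -0.03 for cell cycle (13 of 24 lower), 0.07 for heat shock (7 of 17), 0.27 for autophagy (12 of 30), 0.21 for ribosomal (26 of 76) and 0.11 for histone genes (5 of 14). The ribosomal list passed as higher than the other genes without CNI replicate 1 (3.04e-08) and as lower without abatacept + CNI replicate 2 (2.56e-07), without CNI replicate 2 (0.00254) or 3 (3.04e-05) and with quantile normalization (0.00102). Hematopoietic progenitor markers had a mean of -0.15 (4 of 7, 0.124) and endothelial cell markers -0.22 (4 of 6, 0.191), which were 0.42 (3 of 7) and 0.32 (3 of 6) with median-of-ratios scaling.

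The tests in the next 3 paragraphs were chosen after the results they bear on were seen, except that leaving out each library was planned. NET formation genes and markers of most leukocytes and platelets had lower means together in the abatacept + CNI libraries. CNI replicate 1, however, scored within the abatacept + CNI range for NET (2.90), monocyte (2.47), T cell (0.986) and NK cell genes (1.80). For those lists the lower means rest on CNI replicates 2 and 3. The platelet score of CNI replicate 1, 2.67, lay just above the highest with abatacept + CNI, 2.65. Less leukocyte RNA of every type relative to erythroid RNA, in libraries where ALAS2 averaged 11274 TPM, stays open: 5 of 6 marker lists had a mean below the median of all genes, but these lists are the pattern itself, and the B cell list outside it, at -0.62, was not below. A candidate explanation is that CNI replicate 2 carries the NET difference, since without it the NET list had a camera adjusted p of 0.375, within a range of 2.18e-07 to 0.914 over 20 alternatives, and its mean relative to all genes went from -0.54 to -0.15. Lower NET gene expression per neutrophil under abatacept stays open too, because the NET score minus the mature neutrophil score differed by -0.080 with a standard error of 0.728. How the cells were isolated was not given in the sources used here, and the mature neutrophil list shares 1 gene and the monocyte list 0 genes with the NET list.

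IFI27 averaged 26420 TPM in the abatacept + CNI libraries, above the erythroid gene ALAS2 at 10289 TPM, and 2670 TPM with CNI. More erythroid RNA in these libraries is argued against as an account of the whole IFI27 difference. The erythroid marker score differed by -0.18 with a standard error of 0.200, below the IFI27 difference of 3.84 ± 0.66 (SE). With median-of-ratios scaling the difference was 0.56 for the erythroid markers and 4.59 for IFI27, so a smaller rise in erythroid RNA stays open. A higher type I interferon response across its genes may still be present: the other 32 genes had a median of -0.55, 7 of them were higher, and limma's camera did not set them apart from the other genes (adjusted p = 0.0983 over the 2 lists tested so after the fact). That median lies close to the median of all genes, -0.65, so these values leave the explanation open. Treatment itself stays open as a biological explanation, with IFI27 not past the threshold over all genes.

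SNORA100 was listed at 0 in the 3 abatacept + CNI libraries. Capture of short noncoding RNAs may have differed between the groups. The other 17 short noncoding RNAs tested had a median of -0.49 with 12 lower, where the median of all genes was -0.65. Their direction relative to the other genes was higher, but limma's camera did not set them apart (adjusted p = 0.320). Whether capture or treatment lies behind the SNORA100 values cannot be told apart, because a failed estimate can also give a 0 in TPM.

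The count of genes and lists under other splits of the samples was planned before the data were examined. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split had 1696 genes without overlap and the highest of the others 2255, a count added after the fact. The real split gave 1 gene and the highest of the others 1, and 6 of the 10 splits gave as many. The real split gave 12 lists and the highest of the others 18, and 5 of the 10 splits gave as many.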
